A study of Sus scrofa with 4 samples.

How the data were processed

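RNA from cultured cells labelled as porcine immature spermatogonia, germ cells taken from pig testis, was sequenced in 4 libraries: 2 of control cells and 2 of cells with knockdown of ZBTB16. Samples were assigned to the groups control and ZBTB16 knockdown from their labels, which also number the replicates. The series' design plans knockdown with a short hairpin RNA carried by a lentivirus. The labels give the control cells as WT and do not say whether they received a vector. An effect of the lentivirus itself therefore cannot be told apart from that of the knockdown for any gene. CUT&Tag and immunofluorescence, which the design also plans, were not analysed here.

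Per the labels' protocols, mRNA libraries were sequenced on an MGI instrument. Reads were filtered with SOAPnuke 2.1.0, aligned with HISAT2 2.2.1 to the pig assembly Sscrofa 11.1 and mapped to the transcripts with bowtie2 2.3.5. The authors counted reads with RSEM 1.3.3, which shares a read among the transcripts it fits, so the deposited expected counts need not be whole numbers. Between 83.7% and 84.7% of the deposited expected counts in a library were whole. The authors also deposited FPKM, a fragment count scaled by transcript length and library size, made with RSEM per the labels' protocols. They also deposited TPM, a share of transcripts scaled to the same total in each library, which was not used in the comparisons. Each deposited table also gives a transcript length and an effective length per gene, in bases. The mean fragment length of each library was read from the difference between these deposited lengths. The labels state that the authors used DESeq2 at an unadjusted p threshold of 0.05 for their own list, which was not used here. Whether the counting used strand is not given in the sources used here, so antisense partners and overlapping genes cannot be separated.

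Each table held 26921 genes or loci, of which 638 were unannotated loci without coordinates. All others (100.0%) matched the RefSeq annotation by transcript accession or locus tag, which gave the chromosome, start and end. Gene Ontology terms were attached to 17599 genes and KEGG pathways to 8680, as deposited by the authors.

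Expected counts were rounded to whole numbers and compared between the groups with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, low genes were removed with filterByExpr (minimum count 10, minimum total count 15) and the quasi-likelihood test was two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the words rose and fell are used of called genes. All adjusted p-values of genes come from this fit unless another tool is named. Log2 fold changes are knockdown over control with the standard error of the fit. FPKM is given as mean ± SD of 2 libraries. Its ratio between the groups can differ from the fitted fold change by counts, as for CCL8 and COX6C below. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so the test rests on a spread pooled across genes. The common biological coefficient of variation was 0.0129.

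The groups, the comparison, the tests, 32 gene lists and the rule for named genes were chosen before the data were examined. ZBTB16 came first. Then, among called genes with a gene symbol, a mean FPKM of at least 1 in the higher group and both knockdown libraries on the same side of both control libraries, the 12 with the largest rise and the 12 with the largest fall were named. In each list up to 4 members with the smallest p and a mean FPKM of at least 1 were named, and members of the lists of undifferentiated and differentiating spermatogonia could be named whatever their p. Lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM of the counts with a prior count of 2), adjusted over the lists by Benjamini-Hochberg. Estimated correlations and fry were the alternatives. Terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test of the genes that rose and of the genes that fell. The background was the tested genes kept with any term of that kind, adjusted over all 1750 terms and both directions. Genes whose deposited term names and term identifiers differed in number were left out for that kind. The background held 12765 genes for Gene Ontology and 2751 for KEGG, so term sizes can be below those of all annotated genes.

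Alternatives chosen beforehand were DESeq2 1.42.0, 2 other library scalings, no low-count filter, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with an FPKM of at least 1 in at least 2 libraries, the replicate number as a block, leaving out each library in turn, an unadjusted p threshold and a 2-fold threshold. After the data were seen, 4 alternatives were added: an offset for each gene's effective length in each library, removal of a smooth trend of transcript length per library (mgcv 1.9.3), removal of trends of length and GC content, and leaving out unannotated and mitochondrial loci. Exon GC content was available for 96.9% of the tested genes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

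The methods were tested on simulated data made from the real gene means, library sizes and dispersions, with 200 changed genes among 15613 tested. The edgeR test recovered 55.1% of genes changed 1.25-fold, 80% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and 4.1% of its calls were unchanged genes. DESeq2 recovered 32.7%, 60%, 82% and 98% at these sizes, and 0% of its calls were unchanged genes. With a length trend added to the simulated counts, 95.3% of the edgeR calls were genes without a change of their own. After the trend was removed the share was 2.9% (15619 genes). The trend was fitted to these data and removed with the same kind of smooth fit, so its removal was bound to work. Genes were simulated independently with the fitted dispersions, so these rates need not hold for the real libraries. In the simulated lists camera called the shifted list with the preset correlation and did not call it with an estimated correlation.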

Results

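Expression of all annotated genes was measured in 4 libraries of cells labelled as porcine immature spermatogonia. The aim was to find genes and pathways that depend on ZBTB16, a BTB zinc finger transcription factor known as a marker of undifferentiated spermatogonia. The control libraries held 17283536 and 15983390 expected counts and the knockdown libraries 18500447 and 16548342. Per the labels, the RNA came from 2 independent experiments. Squared differences between the 2 control libraries were 1.15 times those of sampling (chi-square per degree of freedom over 12529 genes). Between the 2 knockdown libraries they were 1.26 times (12401 genes). Only genes with whole counts in both libraries and at least 20 counts over the pair were used. Between a control and a knockdown library the ratio was 25.1 to 27.1. By the median gene it was 6.05 to 6.52 between groups, against 1.13 between the controls and 1.22 between the knockdown libraries. P-values measure only the spread between these samples, which may be technical.

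The libraries also differed by group in properties other than single genes. The mean fragment was 325.7 and 326.7 bases long in the control libraries and 266.4 and 267.3 bases in the knockdown libraries. Mitochondrially encoded genes held 4.15% and 4.29% of control counts and 5.71% of the counts in each knockdown library. Genes of ribosomal proteins held 4.22% and 4.2% of control counts and 2.88% and 2.85% of knockdown counts. Each of these properties separates the libraries exactly as the groups do, so no comparison within a level of them was possible.

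ZBTB16 (chromosome 9, 41639536 to 41839254, Sscrofa 11.1, protein-coding) was lower in both knockdown libraries. Its FPKM was 1.77 and 1.76 in the control libraries and 1.37 and 1.34 in the knockdown libraries, from 226, 207, 188 and 163 counts. The fitted level in the knockdown was 0.779 times that in the control (log2 fold change -0.36, SE 0.109, adjusted p = 0.00338, edgeR). With DESeq2 the log2 change was -0.36 with an adjusted p of 0.109, and with limma on log2(FPKM + 1) it was -0.23 with an adjusted p of 0.0749, so the call depended on the test. Over the alternatives run the adjusted p lay between 5.16e-05, with the length trend removed, and 0.109.

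Of 15763 genes tested, 3574 rose and 3745 fell in the knockdown (7319 called, 48.8% of them higher), and 8444 did not pass. Most changes were small: the median size among called genes was 1.24-fold, and 470 genes changed at least 2-fold (259 higher, 211 lower). With the effective length as an offset 185 were higher and 353 lower at least 2-fold, with limma on log2(FPKM + 1) 78 and 250, and with trends of length and GC content removed 143 and 83. DESeq2 called 4452 genes, all of them among the 7319. With limma on log2(FPKM + 1), which also differs in test, filter and library scaling, 6067 of 13072 genes were called and 34.5% of them were higher. With edgeR and the effective length as an offset 48.5% of 7307 were higher. The 2-fold changes were split by kind of gene. Among genes with a symbol 55 rose and 146 fell at least 2-fold, among annotated genes with only a LOC number 69 and 47, and among the unannotated loci 132 and 18.

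**Figure D1:**
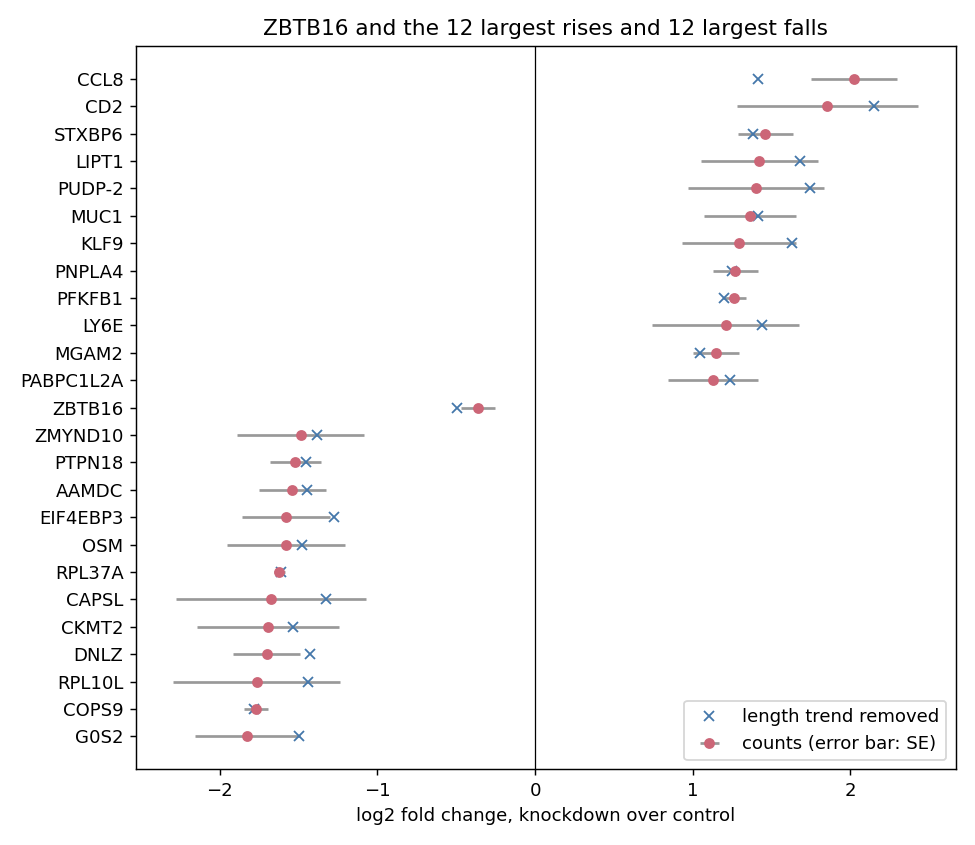
Log2 fold change (knockdown over control, x axis) of ZBTB16 and of the 12 largest rises and 12 largest falls that met the naming rule, with the standard error of the edgeR fit as bars and the value after removal of the transcript length trend as crosses. ZBTB16 lies at -0.36, CCL8 at 2.02 and G0S2 at -1.83.

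Among genes that met the naming rule the largest rise by counts was that of CCL8, a chemokine that attracts monocytes (chromosome 12, 40740468 to 40741970), from 21.7 ± 4.32 to 44.6 ± 1.92 FPKM (SD, n = 2). Its counts rose 4.07-fold (log2 2.02, SE 0.27, adjusted p = 4.08e-11), more than its FPKM. Its transcript is 347 bases long. With the effective length as an offset its log2 change was 1.10, below the 1.77 of CD2. PFKFB1, an enzyme that sets the level of fructose 2,6-bisphosphate, rose 2.40-fold from 4.73 ± 0.53 to 10.9 ± 0.248 FPKM (chromosome X, 47771751 to 47859079, adjusted p = 3.63e-37). STXBP6, a protein that binds SNARE complexes, rose 2.75-fold to 1.85 ± 0.0495 FPKM (adjusted p = 2.95e-13), MGAM2 2.22-fold, MUC1, a membrane mucin, 2.57-fold and PNPLA4 2.41-fold by counts (log2 1.27, and 0.75 with the effective length as an offset). CD2, LIPT1, PUDP-2, KLF9, LY6E and PABPC1L2A completed the 12, with rises of 2.19-fold to 3.62-fold at knockdown means of 1.01 to 3.64 FPKM. PUDP-2 and PABPC1L2A have near-identical gene copies and are uncertain, since the counting could split reads between copies.

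Among genes that met the naming rule the deepest fall by counts was that of G0S2, an inhibitor of lipolysis, to 0.282 times the control level (4.50 ± 0.332 to 2.13 ± 0.0566 FPKM, adjusted p = 9.99e-07). With the effective length as an offset its log2 change was -1.01, against -2.17 for COPS9 and -2.01 for RPL37A. COPS9, a subunit of the COP9 signalosome (chromosome 15, 139260471 to 139264252), fell from 257 ± 20 to 55.4 ± 3.82 FPKM (log2 -1.77, SE 0.0771, adjusted p = 1.17e-50). RPL37A, a protein of the large ribosomal subunit (chromosome 15, 118702198 to 118704974), fell from 1535 ± 16.7 to 367 ± 13.6 FPKM (log2 -1.62, SE 0.0335, adjusted p = 2.49e-95). OSM, the cytokine oncostatin M, fell to 0.334 times its control level, EIF4EBP3, an inhibitor of cap-dependent translation, to 0.335 times, and PTPN18, a tyrosine phosphatase, to 0.348 times. AAMDC, DNLZ, CKMT2, CAPSL, ZMYND10 and RPL10L fell to between 0.294 and 0.357 times, and RPL10L, a copy of another ribosomal protein gene, is uncertain.

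Of these 24 genes, 10 lost their call without 1 of the libraries, and 11 received no adjusted p from DESeq2 because of low counts. LIPT1 had a log2 change of 0.56 with an adjusted p of 0.455 without knockdown replicate 1, KLF9 0.0682 without control replicate 2 and 0.0669 without knockdown replicate 2, and PABPC1L2A 0.0554 without knockdown replicate 1. CD2 had 0.0661 without control replicate 2 and 0.0767 without knockdown replicate 2. LY6E had 0.417 (log2 0.64) without control replicate 1, 0.0763 without knockdown replicate 1 and 0.21 without knockdown replicate 2, and its log2 change was 2.05 without control replicate 2. PUDP-2, with 0 counts in control replicate 2, had 0.456 (log2 0.46) without that library, 0.0808 without knockdown replicate 1 and 0.125 without knockdown replicate 2. Among the falls, RPL10L had 0.0841 without knockdown replicate 2, CKMT2 0.148 and ZMYND10 0.219 (log2 -0.94) without control replicate 1. CAPSL had 0.131 and 0.0706 without control replicates 1 and 2, and 0.175 and 0.0715 without knockdown replicates 1 and 2. With limma on log2(FPKM + 1) the adjusted p was 0.0506 for PNPLA4, 0.157 for LIPT1 and 0.301 for PUDP-2. With the effective length as an offset it was 0.102 for LY6E and 0.0526 for PUDP-2, and with the length trend removed 0.0734 for CAPSL.

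Genes of undifferentiated spermatogonia moved in both directions. Of 25 tested, 4 rose, 5 fell and 16 did not pass, the same counts when adjusted over the list alone. The falls include that of ZBTB16, the targeted gene. As a whole the list did not differ from other genes (camera adjusted p = 0.869). UCHL1, a deubiquitinase used as a gonocyte and spermatogonia marker, fell from 121 ± 0.926 to 87.2 ± 2.69 FPKM, and CD9, a surface tetraspanin, from 193 ± 0.587 to 135 ± 3.35 FPKM (log2 -0.33 and -0.40, adjusted p = 1.24e-10 and 2.14e-22). PIWIL4, a piRNA-pathway protein, fell by 0.49 and EGR4 by 0.73 on the log2 scale. ITGA6, the laminin receptor subunit alpha 6, rose from 25.1 ± 0.601 to 30.8 ± 0.283 FPKM, and FOXO1, TAF4B and SALL4 rose by log2 changes of 0.19, 0.24 and 1.02, SALL4 at 0.26 to 0.51 FPKM. GFRA1, the GDNF receptor, was at 0.59 and 0.67 FPKM (adjusted p = 0.311) and ID4 at 24.6 and 28.4 FPKM (log2 0.11, adjusted p = 0.0769). ID4 passed as higher with the length trend removed (log2 0.18, adjusted p = 0.00216), with the effective length as an offset (0.26, 3.51e-04) and with limma on log2(FPKM + 1) (0.20, 0.0297). Removing the transcript length trend left UCHL1 at -0.02 (adjusted p = 0.784), FOXO1 at 0.09 (adjusted p = 0.0649) and TAF4B at 0.14 (adjusted p = 0.128). With limma on log2(FPKM + 1) the adjusted p of TAF4B was 0.0672. The calls of PIWIL4 (adjusted p = 0.0622) and EGR4 (0.139) were lost without control replicate 1, that of EGR4 also without knockdown replicate 1 (0.0972), and that of TAF4B without control replicate 2 (0.0513) or knockdown replicate 2 (0.06). With DESeq2 the adjusted p was 0.0582 for PIWIL4, 0.141 for EGR4 and 0.127 for TAF4B.

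**Figure D2:**
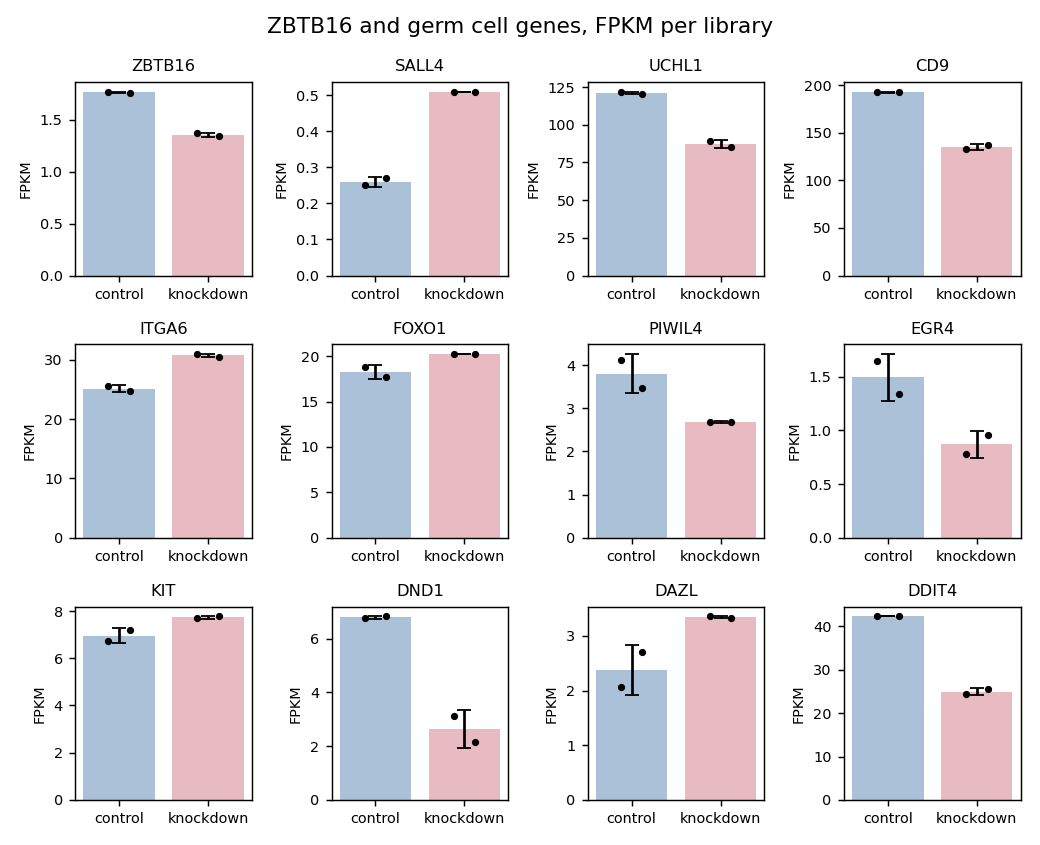
FPKM (y axis, from 0) of ZBTB16 and 11 genes of the germ cell and mTORC1 lists in control and knockdown libraries; bars are means, points the 2 libraries of each group and whiskers the SD. CD9 lies at 193 and 135 FPKM and DND1 at 6.81 and 2.64 FPKM in control and knockdown.

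Of 10 tested genes of spermatogonial differentiation, 3 rose, 2 fell and 5 did not pass; adjusted over the list alone 3 rose and 3 fell (camera adjusted p = 0.906). KIT, the receptor that marks differentiating spermatogonia, rose from 6.97 ± 0.304 to 7.74 ± 0.0636 FPKM (log2 0.23, adjusted p = 0.00196), and SALL1 from 0.22 to 0.475 FPKM (log2 1.16). UPP1 fell by 0.63 and DNMT3B by 0.24 on the log2 scale, while DMRT1 was at 2.46 and 2.93 FPKM (adjusted p = 0.109; 0.0426 with the length trend removed). Removing the length trend left KIT at 0.13 (adjusted p = 0.0912), CCND2 at 0.09 (adjusted p = 0.166) and UPP1 at -0.43 (adjusted p = 0.105). With limma on log2(FPKM + 1) the adjusted p was 0.108 for KIT and 0.102 for DNMT3B. CCND2, a D-type cyclin, rose by counts (log2 0.16, adjusted p = 0.00735) and was lower by FPKM (14.0 ± 1.05 to 12.2 ± 0.0919; log2 -0.19 with limma on log2(FPKM + 1), adjusted p = 0.0481), so its direction depended on the unit. Without control replicate 1 the adjusted p was 0.11 for KIT, 0.123 for CCND2, 0.107 for UPP1 and 0.348 for DNMT3B; without knockdown replicate 1 it was 0.0687 for CCND2 and 0.365 for DNMT3B (log2 -0.15). With DESeq2 it was 0.0866 for KIT, 0.136 for CCND2, 0.163 for UPP1 and 0.328 for DNMT3B.

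Among 15 tested genes expressed throughout the germ line, 4 rose, 2 fell and 9 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.937). DND1, an RNA-binding protein needed for germ cell survival, fell from 6.81 ± 0.0495 to 2.64 ± 0.707 FPKM (log2 -1.27, SE 0.149, adjusted p = 1.39e-13), with a log2 change of -1.59 without knockdown replicate 1 and -1.03 without knockdown replicate 2. DAZL, another germ cell RNA-binding protein, rose 1.46-fold to 3.35 ± 0.0212 FPKM (log2 0.54, and 0.35 without control replicate 1), PIWIL2 1.34-fold to 2.97 ± 0.149 FPKM and TEX15 1.39-fold to 4.30 ± 0.0212 FPKM. Of 15 tested meiosis genes 1 rose, the cohesin STAG3 (3.07 to 4.18 FPKM, adjusted p = 4.72e-06), 0 fell and 14 did not pass, also when adjusted over the list alone. The list's median log2 change was -0.05 although its mean (0.03) and its test were upward (camera adjusted p = 0.906).

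All 41 tested genes of the list of cytosolic ribosomal proteins fell, also when adjusted over the list alone, with a median log2 change of -0.51 (camera adjusted p = 2.37e-18). The list does not hold every such gene. Among genes annotated with the cytosolic large ribosomal subunit 31 of 35 tested fell, and with the small subunit 29 of 35. RPS12 fell from 3884 ± 9.58 to 1425 ± 38.5 FPKM, RPLP2 from 2582 ± 45.3 to 807 ± 4.53 and RPS19 from 2613 ± 8.05 to 909 ± 4.90. By the fitted counts they fell to 0.502, 0.459 and 0.438 times control, less than by FPKM. Of 28 nuclear genes of oxidative phosphorylation 26 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone (median -0.35, camera adjusted p = 9.41e-10). COX6C, a subunit of cytochrome c oxidase, fell from 628 ± 41.5 to 176 ± 1.86 FPKM and COX5B from 603 ± 13.4 to 233 ± 4.75. NDUFB5, a subunit of complex I, fell from 94.3 ± 4.02 to 36.9 ± 0.0354 FPKM. The fitted counts of COX6C, COX5B and NDUFB5 fell less, to 0.398, 0.534 and 0.446 times control. The 12 tested mitochondrially encoded genes all rose, also adjusted over the list alone (median 0.70, camera adjusted p = 1.27e-07), among them KEF22_p02 (ND6, log2 1.45) and KEF22_p03 (ND5, log2 1.04), whose reads can be shared with nuclear copies of mitochondrial DNA. With an estimated correlation the adjusted p was 0.343 for ribosomal proteins, 0.343 for oxidative phosphorylation and 0.448 for the mitochondrial genes. These changes went with the shorter fragments of the knockdown libraries.

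Log2 fold changes rose with transcript length across genes (Spearman 0.37 over 15763 genes, which are not independent replicates). The median log2 change was -0.42 for the 884 genes of 500 to 1000 bases and 0.19 for the 1044 genes of at least 8000 bases, while the 235 genes under 500 bases had a median of 0.70. Removing the length trend left the ribosomal protein list at a median of -0.34 (35 genes lower, 1 higher) and oxidative phosphorylation at -0.25 (21 lower, 3 higher). With trends of length and GC content removed the ribosomal protein list was at -0.15 (camera adjusted p = 1.05e-06).

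**Figure D3:**
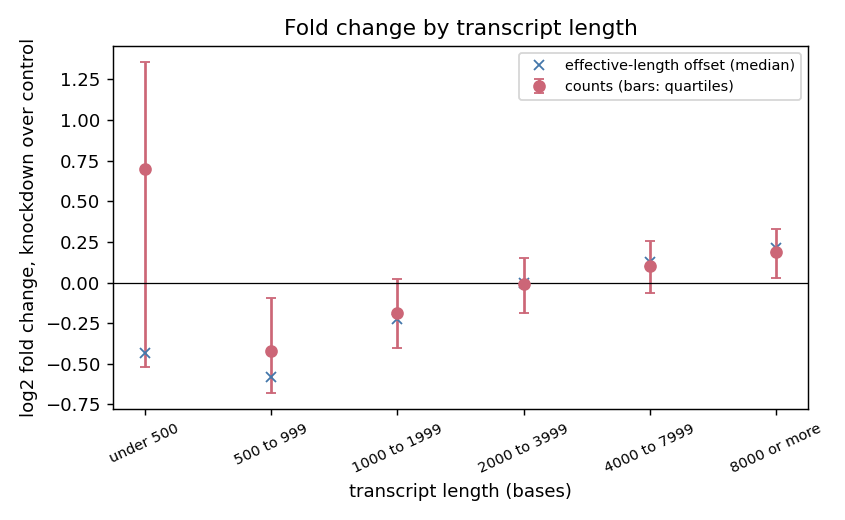
Median log2 fold change of the tested genes (knockdown over control, y axis) by transcript length in bases (x axis); bars span the quartiles and crosses give the median with effective length as an offset. Genes under 500 bases lie at 0.70 by counts and at -0.44 with the offset, and genes of at least 8000 bases lie above 0 both ways.

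Interferon response genes were lower. Of 35 tested, 22 fell, 4 rose and 9 did not pass; adjusted over the list alone 23 fell and 4 rose (median -0.25, camera adjusted p = 4.76e-04; adjusted p = 0.448 with an estimated correlation). ISG15, a ubiquitin-like modifier, fell from 281 ± 3.66 to 96.0 ± 1.06 FPKM, IFI6 from 1142 ± 1.68 to 470.0 ± 4.63 FPKM, and the antiviral enzyme RSAD2 from 20.1 ± 0.545 to 12.1 ± 0.219 FPKM. The median was -0.16 with the length trend removed (camera adjusted p = 5.15e-04) and -0.15 with trends of length and GC content removed (5.89e-04). NF-kB and inflammation genes were mixed, with 9 falls, 4 rises and 10 not passing among 23 tested (10 and 6 adjusted over the list alone; camera adjusted p = 0.165). The acute-phase gene SAA3 fell from 468 ± 22.7 to 220.4 ± 11.2 FPKM and the chemokine CXCL2 from 134 ± 2 to 85.7 ± 0.842, while CXCL8 rose 1.16-fold by counts (adjusted p = 0.0539 with limma on log2(FPKM + 1)).

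Metabolic lists were also lower. Of 21 tested genes of cholesterol synthesis 15 fell, 2 rose and 4 did not pass (15 and 3 adjusted over the list alone; median -0.19, camera adjusted p = 0.00181; adjusted p = 0.448 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 158 ± 0.332 to 116 ± 1.17 FPKM, LSS, the lanosterol synthase, from 65.6 ± 1.98 to 46.7 ± 1.01, and INSIG1, a sterol sensor, from 44.6 ± 0.785 to 29.5 ± 1.37. Of 27 genes of glycolysis and hypoxia 19 fell, 3 rose and 5 did not pass, also adjusted over the list alone (median -0.22, camera adjusted p = 0.00103; adjusted p = 0.461 with an estimated correlation; median -0.11 with trends of length and GC content removed, adjusted p = 0.0411). The glycolytic enzymes TPI1, PGK1 and ENO1 fell to 0.741, 0.773 and 0.829 times their control levels, while ALDOA, an enzyme of the same pathway, rose 1.21-fold. The mTORC1 list went both ways (9 rose, 7 fell and 9 did not pass of 25 tested, also adjusted over the list alone; camera adjusted p = 0.888; mean -0.02, while the median of 0.03 and the test were upward). DDIT4, an inhibitor of mTORC1 also called REDD1, fell from 42.4 ± 0.0141 to 25 ± 0.735 FPKM (log2 -0.69, adjusted p = 5.31e-25), LAMTOR2 fell to 0.523 times, and MLST8, a subunit of the complex, rose 1.60-fold.

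Genes of G2/M and mitosis were higher: 16 of 30 tested rose, 2 fell and 12 did not pass (18 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.018; adjusted p = 0.448 with an estimated correlation; median 0.11 with trends of length and GC content removed, adjusted p = 0.0021). MKI67, a proliferation marker, rose from 15.0 ± 0.0566 to 21.0 ± 0.283 FPKM, TOP2A from 25.5 ± 0.636 to 31.0 ± 0.396 and KIF11, a mitotic kinesin, from 10.2 ± 0.255 to 12.6 ± 0.113. Genes of G1/S and DNA replication split evenly, with 6 rises, 7 falls and 17 not passing among 30 tested, also adjusted over the list alone (median 0.01, while the mean of -0.03 and the test were downward, camera adjusted p = 0.906). MCM4 rose 1.23-fold while MCM7 fell to 0.835 times and FEN1 to 0.693 times. Another list held cyclins, CDKs, CDK inhibitors, RB1, RBL1, MYC and MYCN. Of its 16 tested genes 5 rose, 3 fell and 8 did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.966). RB1 and RBL1 rose 1.28-fold and 1.3-fold. Of 23 p53 target and apoptosis genes 8 fell, 3 rose and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.611). BAX, a pro-apoptotic BCL2 family member, fell from 88.8 ± 3.72 to 37.3 ± 0.523 FPKM and MCL1, an anti-apoptotic member, from 159 ± 0.0424 to 132 ± 1.46.

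Transcripts typical of testis somatic cells were abundant in all libraries. The purity of the cultures is not given in the sources used here, so changes of genes that somatic cells also express, such as CD9 and ITGA6, cannot be assigned to a cell type. FPKM summed over all genes and loci was 739808 and 742383 in the control libraries and 634962 and 632881 in the knockdown libraries. A lower sum for a list is therefore not by itself a lower share. FPKM summed over the Sertoli cell list came to 2951 in control and 3114 in knockdown, and over the peritubular myoid list to 7541 and 7324. The sum for undifferentiated spermatogonia was 441 and 357, of which CD9 held 193 and 135 and UCHL1 121 and 87.2. Over the list of genes expressed throughout the germ line the sum was 52.7 in control and 46.7 in knockdown. Of 20 tested Sertoli cell genes 11 rose, 4 fell and 5 did not pass, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0913; 0.00427 with the length trend removed; adjusted p = 0.461 with an estimated correlation). SOX9, a Sertoli cell transcription factor, rose from 20.9 ± 0.453 to 29.5 ± 0.46 FPKM, CLDN11, a tight junction protein, from 579 ± 11.2 to 706 ± 20.9, and FSHR, the FSH receptor, from 88.6 ± 0.141 to 108 ± 0.481. Of 14 peritubular myoid and smooth muscle genes 9 rose, 3 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.164; 0.0192 with the length trend removed; adjusted p = 0.487 with an estimated correlation). ACTA2, smooth muscle actin, rose from 3204 ± 7.95 to 3474 ± 48.5 FPKM and MYL9 1.27-fold, while TAGLN fell to 0.821 times, a fall absent once trends of length and GC content were removed (log2 0.01). Of 19 fibroblast and stroma genes 10 fell, 3 rose and 6 did not pass (11 and 4 adjusted over the list alone; camera adjusted p = 0.143; 0.0343 with the length trend removed and 0.0935 with trends of length and GC content removed; adjusted p = 0.731 with an estimated correlation), COL3A1 falling from 856 ± 1.43 to 731 ± 5.28 FPKM while LUM rose 1.41-fold. Of 10 Leydig cell genes 3 fell, INSL3 among them (34.4 ± 0.177 to 18.3 ± 3.53 FPKM), 1 rose and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.279). Of 13 macrophage and leukocyte genes 4 fell, 2 rose and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.937), TYROBP falling from 92.0 ± 0.354 to 41.8 ± 5.43 FPKM. Of 11 endothelial genes 1 fell, 0 rose and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.906).

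The TGF-beta and BMP targets were higher as a list: 14 of 23 tested rose, 3 fell and 6 did not pass (15 and 3 adjusted over the list alone; median 0.16, camera adjusted p = 0.0476; adjusted p = 0.448 with an estimated correlation; median 0.08 with trends of length and GC content removed, adjusted p = 0.0411). ID2 rose from 55.1 ± 1.63 to 92.8 ± 2.19 FPKM and CYR61 (CCN1) 1.24-fold. ID1 fell from 259 ± 0.212 to 162 ± 2.1 FPKM and ID3 from 340 ± 6.46 to 218 ± 2.48 FPKM, although all ID genes are known BMP targets. Chromatin partners of ZBTB16 were higher, with 13 rises, 3 falls and 4 not passing among 20 tested (13 and 4 adjusted over the list alone; median 0.17, camera adjusted p = 0.0302; adjusted p = 0.448 with an estimated correlation). The corepressor NCOR1 rose 1.23-fold and RNF2, a Polycomb ubiquitin ligase, 1.34-fold. Its partner RING1 fell to 0.69 times. With the replicate number as a block, neither the TGF-beta and BMP targets nor the chromatin partners of ZBTB16 passed camera. The TGF-beta and BMP targets lost their call without control replicate 1 (adjusted p = 0.062), control replicate 2 (0.0964) or knockdown replicate 1 (0.108). The chromatin partners of ZBTB16 lost it without control replicate 2 (0.0885) and with the length trend removed (median 0.05, adjusted p = 0.104), and kept it with trends of length and GC content removed (median 0.13, adjusted p = 0.0411).

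**Figure D4:**
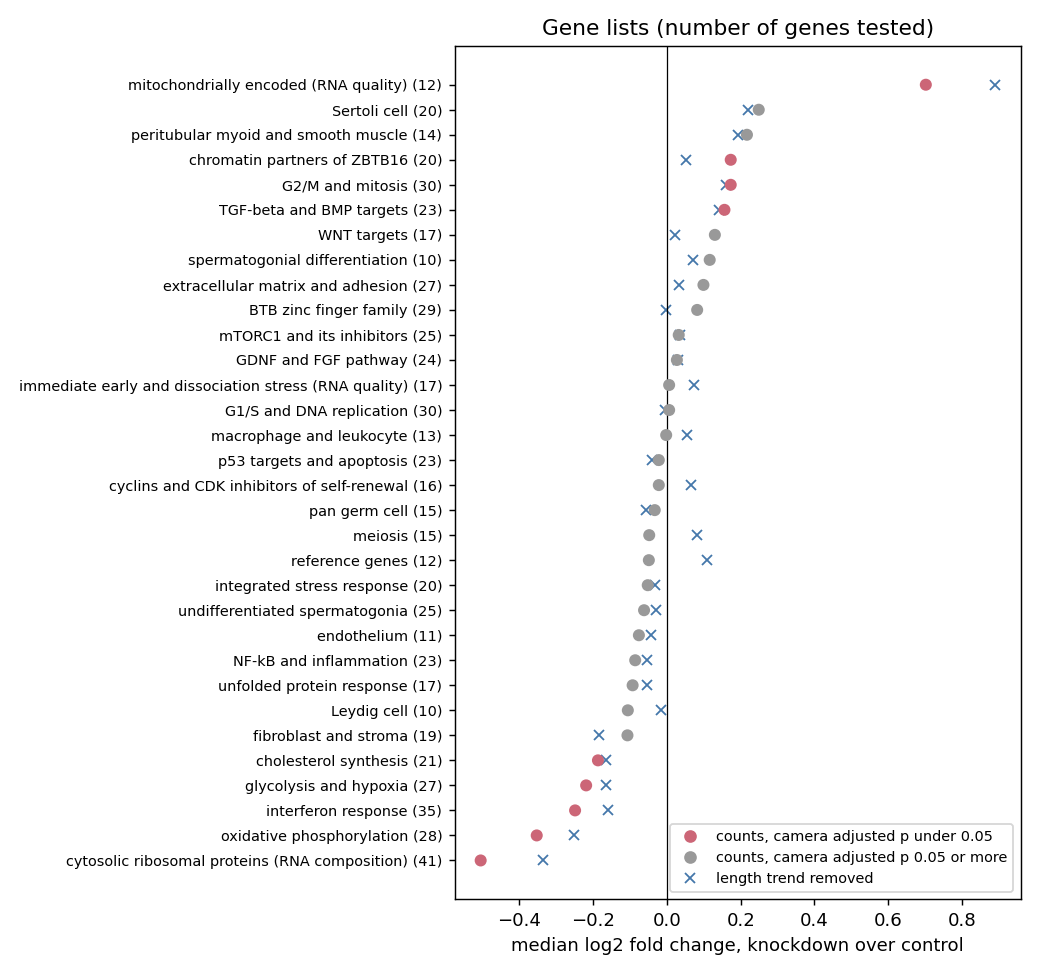
Median log2 fold change (knockdown over control, x axis) of each of the 32 gene lists, with the number of tested genes in parentheses; red points passed camera at an adjusted p under 0.05, grey points did not, and crosses give the median after removal of the length trend. Ribosomal proteins lie at -0.51 and mitochondrially encoded genes at 0.70.

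The remaining lists did not pass camera. Of 24 GDNF and FGF pathway genes 7 rose, 5 fell and 12 did not pass, also adjusted over the list alone (adjusted p = 0.611), with FOSL1 up 1.40-fold and DUSP4 at 0.769 times. Of 17 WNT targets 4 rose, 4 fell and 9 did not pass, also adjusted over the list alone (adjusted p = 0.869), TCF7 rising 1.65-fold. Of 27 genes of extracellular matrix and adhesion 14 rose, 4 fell and 9 did not pass, also adjusted over the list alone (adjusted p = 0.0913). HSPG2, the basement membrane protein perlecan, rose 1.35-fold and the protease MMP14 fell to 0.748 times. Of 29 BTB zinc finger genes 6 rose, 3 fell and 20 did not pass (5 and 3 adjusted over the list alone; adjusted p = 0.203). The falls include that of ZBTB16, the targeted gene, and that of ZBTB7B to 0.781 times. Of 20 integrated stress response genes 8 fell, 2 rose and 10 did not pass (9 and 2 adjusted over the list alone; adjusted p = 0.245), NUPR1 falling from 3029 ± 69.0 to 1320 ± 15.2 FPKM while CEBPB rose 1.47-fold. Of 17 unfolded protein response genes 11 fell, 2 rose and 4 did not pass (11 and 3 adjusted over the list alone; adjusted p = 0.119), MANF falling to 0.649 times. Of 17 immediate early and dissociation stress genes 7 rose, 7 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.923; mean -0.01, while the median of 0.01 and the test were upward), JUN rising 1.24-fold and ATF3 falling to 0.706 times. Of 12 reference genes 5 rose, 6 fell and 1 did not pass, also adjusted over the list alone (adjusted p = 0.937; mean 0.02, while the median of -0.05 and the test were downward), ACTB rising 1.26-fold and GAPDH falling to 0.852 times, a fall absent once trends of length and GC content were removed (log2 0.05).

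Among 1750 annotation terms, 78 were enriched among genes that rose and 73 among genes that fell. Of 163 tested genes annotated as structural constituents of the ribosome 134 fell (42.3 expected, adjusted p = 3.83e-48), as did 97 of 169 genes of the mitochondrial inner membrane (43.8 expected, adjusted p = 2.26e-15). So did 30 of the 40 genes kept for the KEGG proteasome term (12.4 expected, adjusted p = 1.79e-06) and 13 of 18 genes of cholesterol biosynthesis (adjusted p = 0.00318). Actin binding had 82 of 184 genes higher (41.8 expected, adjusted p = 9.48e-09), focal adhesion 56 of 109 (24.7 expected, adjusted p = 1.45e-08) and transcription coactivator activity 45 of 91 (20.7 expected, adjusted p = 3.35e-06). With the length trend removed 89 terms passed, 58 among genes that rose and 31 among genes that fell. Of the 89 terms, 66 were among the 151. The mitochondrial large ribosomal subunit, with 31 of 40 genes lower at first, was no longer enriched (adjusted p = 0.116).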

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

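The tests of unannotated loci were chosen only after the result was seen. The loci were among the genes tested, but the protein hits deposited for them were not used in any comparison. A class of unannotated loci was taken by names in the deposited protein hit, either of certain nematodes and an insect or of the proteins ART2 and TAR1. Such hits were taken as a sign of ribosomal RNA, which was not checked. These loci held 0.424% of counts in the knockdown libraries against 0.0378% in the control libraries (11 of the 12 tested loci rose). Of the unannotated loci, 21 had at most 10 counts over both control libraries and at least 100 over both knockdown libraries, and 0 showed the reverse; 15 of the 21 have no protein hit, and 4 annotated genes showed the same pattern and 0 the reverse. Loci with a hit to a Pol polyprotein or reverse transcriptase held 1.8% of the net gain over all 638 unannotated loci. That share argues against higher expression of LINE and retroviral elements as the main source of the gain. Of the 27 tested loci with such a hit 18 rose and 2 fell, so a rise of these loci themselves is not argued against. Ribosomal RNA left in the knockdown libraries may account for part of the net gain. The loci whose hits were taken as a sign of ribosomal RNA held 38.8% of it, between the bounds set for and against this source. Another 35.7% lay in 5 loci with mitochondrial protein hits, and 12% in loci without a hit. The mitochondrial loci held 0.7636% and 0.7771% of control counts, so they were not near 0 in the controls. The share among loci near 0 in the controls was not computed, so the bounds do not decide for those loci. The loci have no coordinates, so their sequence was not examined, and a response to the knockdown stays open and untested.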

How the results depend on the processing

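The alternatives that use effective length, length or GC trends, or leave out unannotated and mitochondrial loci were chosen only after the data were seen. The count of called genes went from 7319 to 4452 with DESeq2, which gave no adjusted p to 323 of the 7319, and to 470 with a 2-fold threshold; without 1 library it was 6040 to 6265, from fewer samples. ZBTB16 kept its direction in every alternative run and did not pass with DESeq2 (log2 -0.358), limma on log2(FPKM + 1) (-0.232) or log2(FPKM + 0.1) (-0.358); the cause was not tested. Without 1 library its log2 change was -0.337 to -0.387. Of the 32 gene lists 9 passed camera, against 0 with estimated correlation (3 at an unadjusted p under 0.05), 19 with fry, which does not compare a list with other genes, and 7 to 9 without 1 library. Enriched terms numbered 151, against 89 with the length trend removed, 133 from calls at an unadjusted p and 181 from DESeq2 calls. Among the genes named in the text, changes of direction were seen for CCND2 (log2 -0.188 and -0.201 on the 2 FPKM scales, -0.149 with the effective-length offset), TAGLN (0.01) and GAPDH (0.046), the last 2 with length and GC trends removed; the cause was not tested. Of all 7319 calls, 365 changed sign with the length trend removed (2027 no longer passed), 490 with length and GC trends removed, 129 with the effective-length offset and 138 with limma on log2(FPKM + 1). With the replicate number as a block 7480 genes and 7 lists were called, and ZBTB16 stayed at -0.36. The lists that no longer passed were the TGF-beta and BMP targets and the chromatin partners of ZBTB16. The control and knockdown differences between replicates 1 and 2 had a correlation of 0.044 across 11060 genes. Libraries of a group differed by little more than sampling, so this correlation cannot show whether same-numbered libraries share an experiment.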

Other observations

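The tests of effective length, of genes outside the ribosomal protein list and of macrophages were chosen only after the result was seen. For ribosomal proteins the pattern was narrowed to their genes, and for histones a version with the length trend removed was looked at first. All intervals below come from resampling genes within the same libraries. Genes are not independent replicates, so the intervals do not measure spread between samples.

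Of 123 tested genes annotated with mRNA splicing via the spliceosome 59 fell (Fisher's exact test, adjusted p = 1.58e-05). By contrast, 19 of 40 annotated with mRNA 3'-UTR binding rose (same test, adjusted p = 0.0166). These terms were picked from the enriched ones, and RNA handling as a whole was not tested. Of 43 annotated with RNA-directed DNA polymerase activity 24 rose (adjusted p = 2.58e-04). FPKM summed over the macrophage and leukocyte list was 152 in control and 92.6 in knockdown libraries, of which TYROBP alone held 92.0 and 41.8, and over the fibroblast and stroma list 3489 and 3155. FPKM summed over all genes and loci was also lower in the knockdown libraries, so these sums do not give shares.

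Transcripts of 500 to 1000 bases were lower in the knockdown libraries and long ones higher, while those under 500 bases were higher by counts. Shorter fragments acting through effective length would raise short transcripts, by a median log2 change of 0.209, while the genes under 1000 bases had -0.36 (95% interval -0.397 to -0.325), so the tables argue against it there; under 500 bases the offset removed 162.9% of the rise, more than all of it, leaving -0.436. A fall of ribosomal protein genes may add to the trend in those genes, whose median stayed at -0.337 with the length trend removed (0% of 5000 random lists matched on length and expression were as low) and was -0.151 with the GC trend removed as well, not compared with random lists, but 800 genes of 500 to 1000 bases outside them had -0.403. Weaker selection of polyadenylated RNA cannot be told apart from the knockdown: 24 histone genes were higher by 0.314 (0.134 to 0.683) than genes of their length, and histone genes also follow the cell cycle. Fragment length and group coincide in all 4 libraries, so a difference in preparation and a biological response both stay open.

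Interferon response genes were lower in the knockdown libraries. The length trend is argued against as the whole source, since their median was -0.249 before and -0.161 (-0.192 to -0.121) after its removal. It may hold a part: falls in the list went from 22 to 16, and the term defense response to virus (30 of 66 genes lower, adjusted p = 0.0166) was no longer enriched (19 lower, adjusted p = 0.725). Fewer macrophages and leukocytes might contribute and cannot be told apart from a response to the knockdown, because that list moved both ways (median -0.002, interval -0.495 to 0.203). Whether the control cells received a vector is not given in the sources used here, so a response to the vector itself was not tested.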
